A study of Mus musculus with 16 samples.

How the data were processed

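RNA was taken from the duodenum and the ileum of 8 male mice, 4 with and 4 without the recombinase, and sequenced as stranded total RNA after depletion of ribosomal RNA. The library titles carry the same 8 numbers in both tissues, read here as mouse numbers, so that the same mouse gave both tissues. As a check, residuals of each duodenum library, after the mean of its group was removed, correlated best with the ileum library of the same mouse in all 8 mice (r of 0.22 to 0.48, against -0.11 to 0.24 for the best other mouse). The groups follow the genotype and tissue stated in the labels. Per the submitters' processing notes, the tools used were cutadapt 1.10, Bowtie2 2.2.8, STAR 2.5.3a and HTSeq 0.6.1p1, with the mm39 assembly. The strand setting of the counting and the annotation release are not given in the sources used here. The deposited values are raw counts per gene, whole numbers for 55359 Ensembl genes in 16 libraries, and the authors' counts were used as they stand. Gene names came from GENCODE release M21, built on an earlier assembly than the authors' and used for names alone. It named 52083 of the identifiers, while 3276 stayed unnamed and held 1.02% of all counts. No count in any library was recorded for 21034 identifiers. No library pair was identical. Reads of near-identical paralogs (defensin, mast cell protease, Reg, glutathione transferase, immunoglobulin and pancreatic protease genes) may be split or discarded in counting, so the level of a single member of these families is uncertain.

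Totals were 40.9 to 67.2 M counts per library, so 3 counts over the 4 libraries of a group, the floor used where a group had none, is below 0.02 CPM. Genes with 0 counts in a group are given as at least so many fold lower or higher against that floor, and genes with 1 to 3 counts as a ratio with a 95% counting interval. CPM values were computed from library sizes scaled by the trimmed mean of M values, and log2 CPM values with a prior count of 2.

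Each tissue was fitted on its own with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes were kept by the filterByExpr rule, libraries were scaled by the trimmed mean of M values, and genotype was tested with the robust quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and also over each gene list alone, with a threshold of 0.05. The genotype by tissue comparison and the tissue contrasts within each genotype came from a fit to all 16 libraries or to the 8 libraries of a genotype. The lists of marker and pathway genes (45 lists with 644 members, of which 1 member was not found) were written before the data were examined, as were the grouping, the tests and the first set of alternatives. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry.

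Genes are named by rule. Neurog3, Gcg, Gip, Cck and Chga are always named. To these are added the 8 largest rises and 8 largest falls per tissue among genes with an adjusted p under 0.05, a mean of at least 1 CPM and all 4 mutant libraries on the same side of all controls, up to 4 members with the smallest p per list discussed, the 8 smallest p-values of the genotype by tissue comparison, and 6 genes in each direction between tissues. Other genes are said to have been chosen after their values were seen. Some genes that meet the rule are not reported here.

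Alternatives tried were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, limma-voom, no low count filter, a filter of 1 CPM in 4 libraries, each mouse left out in turn, all 16 libraries in 1 fit, smooth muscle genes as a covariate, a test against a fold change of 1.5, and the mouse as a block. After seeing the data, fits without control mice C134 and C154, without mutant mice M167 and M177, and with the exocrine pancreas or the lymphoid follicle genes as a covariate were added. The tests were also run on simulated data in which 200 genes were changed. At fold changes of 1.5, 2 and 4, edgeR recovered 5.97, 58.2 and 83.3% of them in the duodenum setting, 14.9, 53.7 and 87.9% in the ileum setting and 5.97, 31.3 and 71.2% in the genotype by tissue setting. In the tissue setting of control mice it recovered 25.4, 59.7 and 90.9%, and in that of mutant mice 5.97, 38.8 and 80.3%. Of the calls, 6.67, 6.31, 1.37, 7.87 and 0% were false in these 5 settings, and for DESeq2 27.9, 24.5 and 24.8% in the first 3. Camera at the preset correlation called 2 of 44 lists that had not been raised in the genotype by tissue setting and 0 in the others. Simulated counts were drawn independently for each gene and library, without links between genes or between libraries of a mouse. These shares therefore need not hold for the real data.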

Results

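Total RNA was profiled from the duodenum and the ileum of adult male C57BL/6N mice that ate a high fat diet. Mutant mice carried floxed Neurog3 alleles together with CreERT2, a tamoxifen-dependent recombinase driven by the Villin promoter, which is active in the intestinal epithelium. Control mice carried the floxed alleles without the recombinase. Neurog3 is the transcription factor that starts the differentiation of enteroendocrine cells, the hormone-secreting cells of the gut epithelium, and the study asked what both tissues transcribe when these cells are missing. There were 4 control mice (C133, C134, C151 and C154) and 4 mutant mice (M136, M167, M168 and M177), sampled 5 weeks after tamoxifen, and each mouse gave 1 library per tissue. C and M before a mouse's number in the labels stand for control and mutant. The 16 libraries held 40.9 to 67.2 M counts, with a mean ± SD of 59.5 ± 5.83 M in control duodenum, 54.1 ± 6.24 M in mutant duodenum, 47.3 ± 7.56 M in control ileum and 51.7 ± 3.19 M in mutant ileum. Levels are given in counts per M (CPM) as mean ± SD over the 4 libraries of a group. Log2 fold changes are mutant over control unless another direction is named, and a gene is said to have risen or fallen where edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05.

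The libraries separated first by tissue, along a principal component that held 44.0% of the variance. The second component held 20.2% and ran from -68.9 to -17.3 in the mutant libraries and from 10.3 to 67.7 in the control libraries, where control mice C134 and C154 lay at 59.9 to 67.7 and control mice C133 and C151 at 10.3 to 27.8. Transcripts of digestive enzymes typical of the exocrine pancreas differed widely between mice. A list of 12 such genes took 0.721, 14.9, 3.41 and 14.7% of all counts in the duodenum of mutant mice M136, M167, M168 and M177. The same genes took 2.46 and 1.66% in the duodenum of control mice C133 and C151, but 0.0064 and 0.0068% in that of control mice C134 and C154. In the ileum their share was between 0.0119 and 0.361%. None of the 12 genes passed the test in the duodenum or, for the 11 tested, in the ileum, with median log2 fold changes of 3.10 and 1.71 (camera adjusted p = 0.00063 and 0.047, and adjusted p = 0.71 and 0.70 with an estimated correlation), and none passed when adjusted over the list alone. Transcripts of organised lymphoid tissue also set the controls apart, shown here by a gene chosen after its values were seen. Cr2, a complement receptor of B cells and follicular dendritic cells, stood at 6.88 and 13.1 CPM in the duodenum and 27.4 and 27.2 CPM in the ileum of control mice C134 and C154, against at most 1.77 CPM in any other library.

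The targeted gene was almost absent from the mutant libraries of both tissues. Neurog3 (ENSMUSG00000044312) stood at 2.59 ± 0.145 CPM in control duodenum (549 counts over the 4 libraries) against 1 count over the 4 mutant libraries, a ratio of 459 with a 95% counting interval of 82.1 to 18172 (adjusted p = 6.11e-06). In the ileum it stood at 0.890 ± 0.224 CPM (201 counts) against 1 count, a ratio of 223 with an interval of 39.5 to 8840 (adjusted p = 4.32e-05). These intervals, and the floor of 3 counts over a group used for genes without a count, cover counting error only.

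In the duodenum, 10 of 13 hormone genes of the enteroendocrine lineage fell in mutant mice, some of them to the edge of detection. Gip, which encodes the incretin GIP, fell from 74.7 ± 18.9 to 0.0937 ± 0.0396 CPM (log2 fold change -9.63, SE 0.30, adjusted p = 8.48e-08). Cck, which encodes the satiety hormone cholecystokinin, fell from 50.9 ± 7.39 CPM to 3 counts over the 4 mutant libraries, a ratio of 2997 with an interval of 1025 to 14535 (adjusted p = 2.22e-07). Ghrl, the ghrelin gene, fell by 9.53 on the log2 scale (SE 0.42, adjusted p = 1.53e-06), and Tph1, which starts serotonin synthesis in enterochromaffin cells, fell by 9.08 (SE 0.32, adjusted p = 1.71e-07). None of the 13 rose, and 11 fell when adjusted over the list alone. The median log2 fold change of the list was -4.42 (camera adjusted p = 1.2e-18, and adjusted p = 0.0029 with an estimated correlation). Sst and Sct, which encode somatostatin and secretin, kept measurable levels and fell from 61.7 ± 11.7 to 4.58 ± 0.985 CPM (log2 fold change -3.74) and from 25.5 ± 2.91 to 2.22 ± 0.644 CPM (log2 fold change -3.49). Gcg, the precursor gene of GLP-1 and glucagon, did not pass the test (log2 fold change -4.57, SE 1.32, adjusted p = 0.0808). It stood at 22.5 ± 7.62 CPM in controls and at 0, 0.118, 0.167 and 3.68 CPM in mutant mice M136, M167, M168 and M177. Gcg passed without mutant mouse M177 (adjusted p = 0.00168), without M167 and M177 (0.0163), with limma-voom (0.0235) and with all 16 libraries in 1 fit (0.00984), with a range of 0.00168 to 0.282 over all alternatives. The duodenum of M177 also held the most Ins2, the insulin transcript of pancreatic islets, at 17.4 CPM (a gene chosen after its values were seen).

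**Figure D1:**
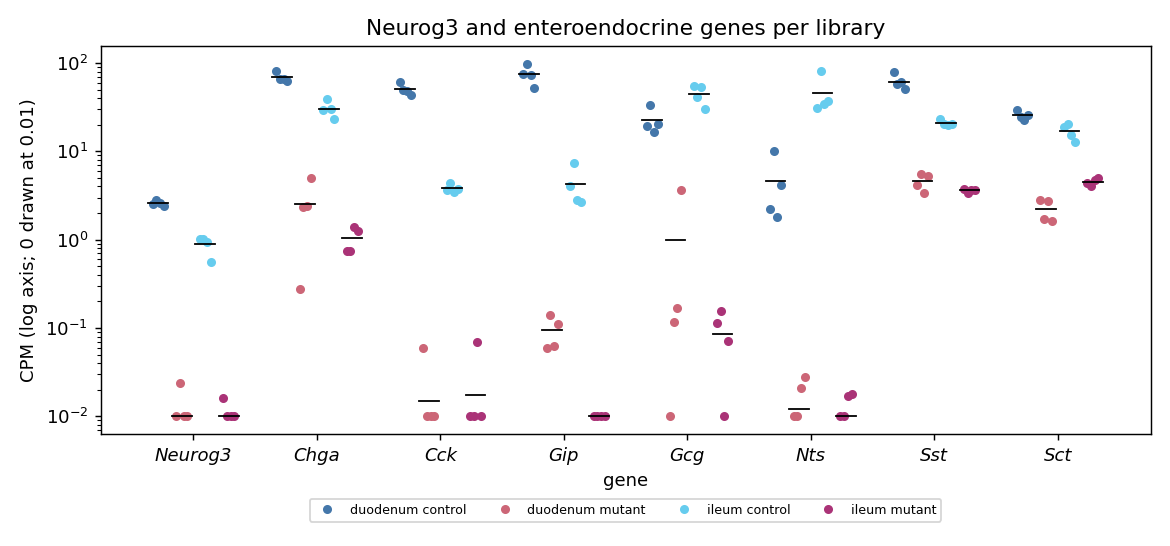
CPM of Neurog3 and 7 enteroendocrine genes in each of the 16 libraries, on a log axis with a value of 0 drawn at 0.01 CPM; points are mice and horizontal lines are means of the 4 libraries of a group. The mutant libraries of both tissues lie below the control libraries for each gene, including Gcg, at 3.68 CPM in the duodenum of mutant mouse M177.

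The transcription factors that act downstream of Neurog3 fell with the hormones. Lmx1a, a regulator of serotonin-producing cells, stood at 2.49 ± 0.276 CPM in controls and had no count in mutants, at least 146-fold lower (adjusted p = 7.14e-05). Neurod1 fell from 6.34 ± 0.561 to 0.0261 ± 0.0522 CPM (adjusted p = 0.000156), and Rfx6 fell from 1.88 ± 0.240 to 0.0558 ± 0.0468 CPM (adjusted p = 0.00031). Of 13 such genes tested 12 fell and none rose, also when adjusted over the list alone (median log2 fold change -4.63, unchanged with the 3 genes without counts in mutants set at their bound, camera adjusted p = 8.2e-17, and adjusted p = 0.0029 with an estimated correlation). Genes of the secretory machinery followed less uniformly: 12 of 21 fell and none rose, and 14 fell and 1 rose when adjusted over the list alone. Their median log2 fold change was -0.80 (camera adjusted p = 4e-09, but adjusted p = 0.18 with an estimated correlation). Among them, the granule protein gene Chgb fell from 53.6 ± 11.4 to 0.471 ± 0.295 CPM (adjusted p = 7.14e-05), and the prohormone convertase gene Pcsk1, which is also expressed outside this lineage, fell from 26.8 ± 0.844 to 8.86 ± 2.02 CPM (adjusted p = 0.000556). Chga, the chromogranin A gene, fell from 69.1 ± 8.69 to 2.51 ± 1.95 CPM (log2 fold change -4.79, SE 0.71, adjusted p = 0.0144). Its call ended without mutant mice M167 and M177, without control mice C134 and C154, and with the exocrine pancreas genes as a covariate. Over all alternatives its adjusted p-values were 2e-09 to 0.0974 and its sign did not change. With 1 mouse left out its log2 fold change was -5.37 to -4.41. The list of receptor genes for nutrients, which also holds receptors for gut hormones, had 4 of 11 genes lower, also when adjusted over the list alone. Its median log2 fold change was -0.38 (camera adjusted p = 0.0044, but adjusted p = 0.18 with an estimated correlation). This call ended with the filter of 1 CPM in 4 libraries (adjusted p = 0.0977, 0.000561 to 0.0977 over all alternatives). The fatty acid receptor gene Ffar1 fell by 4.26 (SE 0.43, adjusted p = 0.00052) and the irritant channel gene Trpa1 fell from 13.4 ± 2.07 to 0.948 ± 0.772 CPM (adjusted p = 0.00471).

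Over all genes, 606 were higher and 900 lower in mutant duodenum among 17611 tested (5143 at an unadjusted p under 0.05), and 153 and 299 of these differed at least 2-fold. Outside the enteroendocrine lists, 7 of 9 MHC class II genes, 9 of 18 interferon response genes and 11 of 14 macrophage and dendritic cell genes fell, while 7 of 12 Paneth cell genes and 10 of 25 cholesterol synthesis genes rose. The counts over all genes changed when a mouse was left out, and fell whichever control mouse it was. Of the genes called with all mice, 0 changed sign in these fits. The fits also had fewer libraries, so a lower count need not mean that the mouse left out carried the calls. Without control mouse C133, C134, C151 or C154 they were 131 and 410, 129 and 413, 124 and 352, and 216 and 476, and without mutant mouse M167 or M177 they were 314 and 547, and 216 and 442. Without mutant mouse M136 or M168 they were 1025 and 1114, and 916 and 1077. Of alternatives chosen after seeing the data, 140 and 305 genes passed without mutant mice M167 and M177, 37 and 163 without control mice C134 and C154, and 47 and 193 with the exocrine pancreas genes as a covariate. The list mean used as that covariate was itself 11.2 ± 2.13 log2 CPM in mutant and 3.85 ± 7.12 log2 CPM in control duodenum. It overlaps with genotype, so a call lost with it need not mean a pancreatic source.

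Among the largest rises in mutant duodenum was Esr1, the oestrogen receptor gene, from 3.09 ± 0.831 to 38.4 ± 11.4 CPM (log2 fold change 3.65, SE 0.27, adjusted p = 0.000175). Reg2, a regenerating protein gene of pancreatic acinar cells, rose from 1.23 ± 1.99 to 1712 ± 1476 CPM (log2 fold change 10.47, SE 2.19, adjusted p = 0.0388), and its mutant levels moved with those of Ctrb1, a chymotrypsinogen gene of the exocrine pancreas. Reg3b, an antimicrobial lectin gene, rose from 77.9 ± 69.0 to 1973 ± 1232 CPM (log2 fold change 4.67, SE 0.77, adjusted p = 0.0171). Cfap61, a gene of motile cilia, rose from 0.244 ± 0.0785 to 2.32 ± 0.879 CPM (adjusted p = 0.000794), and Azgp1, a secreted glycoprotein gene, from 0.0430 ± 0.0197 to 3.48 ± 2.86 CPM (adjusted p = 0.00875). Rab26, C2cd4b and Cpn2 rose by 4.28, 3.36 and 3.51 on the log2 scale (adjusted p = 0.0282, 0.0331 and 0.0173). In mutant mice M136, M167, M168 and M177, Azgp1 stood at 0.637, 6.75, 1.59 and 4.93 CPM and Rab26 at 0.358, 3.35, 0.939 and 3.74 CPM, beside Ctrb1 at 1387, 35170, 7639 and 35135 CPM, and C2cd4b stood at 0.438, 4.32, 0.814 and 2.19 CPM. With the exocrine pancreas genes as a covariate, the log2 fold changes of Azgp1, Rab26 and C2cd4b were 4.84, 2.60 and 2.49 (adjusted p = 0.129, 0.196 and 0.309). Large falls were also seen for the adhesion receptor gene Adgrg4 (24.3 ± 4.65 CPM in controls against 1 count, a ratio of 4215 with an interval of 756 to 166522), the ion channel gene Asic5 (2.01 ± 0.570 CPM against 0, at least 121-fold lower) and the neurotensin gene Nts (4.57 ± 3.86 CPM against 2 counts, a ratio of 436 with an interval of 120 to 3607). The call for Reg2 ended without any 1 of control mice C133, C134, C151 and C154 or mutant mice M167, M168 and M177 (adjusted p up to 0.115), and that for Reg3b without control mouse C134 (adjusted p = 0.0619). Rab26 lost its call without C133, C134, C151, C154, M167 or M177 (up to 0.0860), C2cd4b without C133, C134, C151, C154 or M177 (up to 0.0945) and Cpn2 without C133 or C151 (up to 0.0608). Over all alternatives adjusted p reached 0.147 for Reg2, 0.113 for Reg3b, 0.215 for Rab26, 0.309 for C2cd4b, 0.162 for Cpn2, 0.140 for Azgp1 and 0.0789 for Nts.

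**Figure D2:**
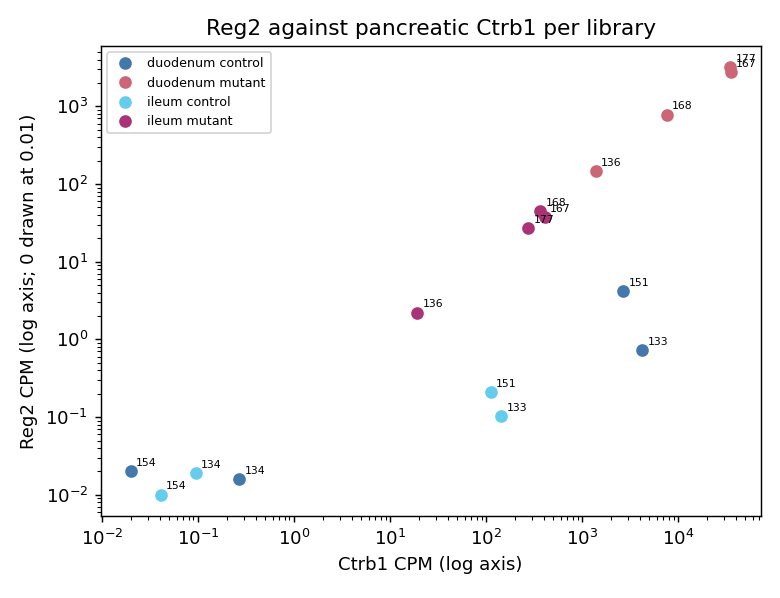
Reg2 against Ctrb1, both in CPM on log axes, 1 point per library labelled by mouse, with a value of 0 drawn at 0.01 CPM. The 8 mutant libraries of both tissues lie along 1 line, with Reg2 at 7.82 to 12.3% of Ctrb1, above control mice C133 and C151.

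Paneth cell genes, which encode the antimicrobial products of the crypt base, rose in mutant duodenum: 7 of 12 rose and none fell, and 11 rose when adjusted over the list alone. The list had a median log2 fold change of 0.79 (camera adjusted p = 4.2e-09, but adjusted p = 0.31 with an estimated correlation). The defensin genes Defa22 and Defa21 rose from 1.32 ± 0.537 to 10.2 ± 4.02 CPM (adjusted p = 0.00273) and from 1.25 ± 0.697 to 11.9 ± 4.99 CPM (adjusted p = 0.0064), and Defa30 from 307 ± 28.4 to 507 ± 46.2 CPM (adjusted p = 0.00875). The defensin copies are near-identical, so counts could be split between them. Mmp7, the protease that activates these defensins, rose from 62.4 ± 16.7 to 124 ± 21.5 CPM (adjusted p = 0.0136), a call that ended without control mouse C134 (adjusted p = 0.0512, up to 0.109 over all alternatives). Genes of cholesterol synthesis rose in 10 of 25 cases and none fell, and 16 rose when adjusted over the list alone. Across the list the median log2 fold change was 0.51 (camera adjusted p = 5.7e-07, but adjusted p = 0.56 with an estimated correlation). Mvk and Lss, which encode mevalonate kinase and lanosterol synthase, each rose by 0.99 (adjusted p = 0.00709 and 0.0119). With the exocrine pancreas genes as a covariate 1 cholesterol gene and 6 Paneth cell genes rose, without control mice C134 and C154 these counts were 0 and 5, and without mutant mice M167 and M177 they were 6 and 4. The list medians in these fits were 0.51, 0.53 and 0.52 for cholesterol genes and 0.91, 0.91 and 0.67 for Paneth cell genes. Over all alternatives adjusted p reached 0.0529 for Mvk, 0.137 for Lss and 0.0552 for Defa30. Without mouse C133, C134, C151, C154 or M177 alone, 4, 3, 4, 6 or 5 cholesterol genes rose, and without mouse C134, 4 Paneth cell genes did.

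Antigen presentation and interferon response genes were lower in mutant duodenum. The MHC class II chain genes H2-Eb1 and H2-Ab1 each fell by 1.15, from 204 ± 15.5 to 91.1 ± 8.73 CPM (adjusted p = 0.000297) and from 269 ± 23.9 to 120 ± 10.6 CPM (adjusted p = 0.000322). Of 9 MHC class II genes 7 fell and none rose, and 8 fell when adjusted over the list alone. Their median log2 fold change was -1.07 (camera adjusted p = 8.7e-09, but adjusted p = 0.18 with an estimated correlation). Stat2, which transmits interferon signals, fell from 55.0 ± 8.93 to 20.8 ± 1.34 CPM (adjusted p = 0.000259). Of 18 interferon response genes 9 fell and none rose, and 17 fell when adjusted over the list alone. Over these genes the median log2 fold change was -1.21 (camera adjusted p = 4.2e-11, but adjusted p = 0.44 with an estimated correlation). The complement genes C1qb and C1qa of tissue macrophages fell by 0.72 and 0.65 (adjusted p = 0.000773 and 0.0017), and Flt3, a dendritic cell receptor gene, by 1.42 (adjusted p = 0.0013). In this list 11 of 14 genes fell and 1 (Cd163) rose, also when adjusted over the list alone. The median log2 fold change of the list was -0.62 (camera adjusted p = 3.4e-08, but adjusted p = 0.066 with an estimated correlation). Without control mice C134 and C154, whose libraries held the follicle transcripts, 7 MHC class II, 7 interferon and 4 macrophage genes still fell. Without mouse C133, C134, C151 or M177 alone, 4, 5, 5 or 5 interferon genes fell, and without mouse C133, C151 or C154, 7 macrophage and dendritic cell genes did.

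In mutant duodenum, of 15 T cell genes 6 fell, 10 when adjusted over the list alone, and none rose. The T cell median log2 fold change was -0.86 (camera adjusted p = 1.1e-06, but adjusted p = 0.52 with an estimated correlation). Cd4 fell by 0.70 (adjusted p = 0.0139) and Cd2 by 1.40 (adjusted p = 0.0231), and no T cell gene passed without control mice C134 and C154, without mutant mice M167 and M177, or with the exocrine pancreas genes as a covariate. The log2 fold change of Cd4 was -0.68, -0.68 and -0.64 in these 3 fits (adjusted p of 0.000202 to 0.119 over all alternatives), and the list medians were -0.89, -0.57 and -0.79. Without mouse C134, C151, C154, M167, M168 or M177 alone, 1, 2, 2, 2, 10 or 2 T cell genes fell. Cd2 also lost its call without mouse C134, C154 or M177 (adjusted p up to 0.0692, and up to 0.222 over all alternatives). Of 24 genes of fatty acid oxidation 4 fell, 8 when adjusted over the list alone, and none rose (median log2 fold change -0.47, camera adjusted p = 5.5e-06, but adjusted p = 0.63 with an estimated correlation), among them Cpt2, which imports fatty acids into mitochondria, from 256 ± 25.1 to 145 ± 24.7 CPM (adjusted p = 0.00811). No gene of this list passed without control mice C134 and C154 or with the pancreas covariate, where Cpt2 had log2 fold changes of -0.90 and -0.85 (adjusted p = 0.0511 and 0.0512, 4.9e-06 to 0.0512 over all alternatives). Without mouse C133, C134, C151, C154, M136, M167, M168 or M177 alone 1, 2, 1, 1, 9, 1, 2 or 2 fell. Of 20 proliferation genes 2 rose, 7 when adjusted over the list alone (median log2 fold change 0.29, camera adjusted p = 0.00039, but adjusted p = 0.71 with an estimated correlation), and without mouse C133, C134, C151, C154, M136, M167, M168 or M177 the 2 became 0, 0, 1, 0, 4, 1, 0 or 0. The goblet cell list was raised as a set although none of its 14 genes passed over all genes and 6 rose when adjusted over the list alone. The list had a median log2 fold change of 0.39 (camera adjusted p = 0.0039, but adjusted p = 0.53 with an estimated correlation), with its highest member at 3.01. The list mean was 7.08, 7.54, 7.52 and 7.73 log2 CPM in M136, M167, M168 and M177. In controls it was 6.81 to 7.08, so M136 lay within their range. The set of 24 lipid uptake genes was lowered with no member past the test, also over the list alone. Across the list the median log2 fold change was -0.35 (camera adjusted p = 0.0039, but adjusted p = 0.82 with an estimated correlation). Of 16 clock genes, the repressor gene Nr1d1 fell from 122 ± 27.9 to 35.7 ± 14.1 CPM (adjusted p = 0.0139) and Nfil3 rose from 4.59 ± 1.18 to 15.7 ± 5.27 CPM (adjusted p = 0.0064). Without control mice C134 and C154 and with the pancreas covariate their calls ended, with log2 fold changes of -1.68 and -1.68 for Nr1d1 (adjusted p = 0.0919 and 0.0987) and 1.85 and 1.82 for Nfil3 (adjusted p = 0.0847 and 0.0619). The call for Nr1d1 also ended without mutant mice M167 and M177 (-1.99, adjusted p = 0.0550), and over all alternatives adjusted p was 1.33e-08 to 0.0987 for Nr1d1 and 4.9e-09 to 0.0847 for Nfil3. Cry2 rose by 0.71 (adjusted p = 0.0241), a call lost without mouse C133, C134 or M177 (up to 0.0690, and up to 0.204 over all alternatives), and the clock list as a whole was not called. The clock median was -0.06 (camera adjusted p = 0.76, with 3 up and 3 down when adjusted over the list alone).

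In the ileum the hormone genes of the distal gut fell too. Gcg fell from 44.9 ± 11.4 to 0.0851 ± 0.0660 CPM (log2 fold change -8.91, SE 0.45, adjusted p = 1.9e-05) and Pyy, which encodes the appetite-lowering peptide YY, from 19.3 ± 5.79 to 0.0176 ± 0.0204 CPM (log2 fold change -10.00, SE 0.47, adjusted p = 4.38e-06). Nts fell from 45.8 ± 23.4 CPM to 2 counts over the 4 mutant libraries, a ratio of 5508 with an interval of 1524 to 45490 (adjusted p = 3.22e-05), and Gip from 4.25 ± 2.24 CPM to no count, at least 349-fold lower (adjusted p = 0.000159). Cck and Tph1 fell by 7.65 and 7.76 on the log2 scale (adjusted p = 3.61e-05 and 2.86e-06). Sst again kept a level above the floor, falling from 21.1 ± 1.59 to 3.62 ± 0.159 CPM (adjusted p = 6.02e-07). Of 12 hormone genes 11 fell, 12 when adjusted over the list alone (median log2 fold change -7.71, or -7.33 with the 2 genes without counts in mutants at their bound, camera adjusted p = 8e-13, and adjusted p = 0.032 with an estimated correlation). Adgrg4 stood at 8.01 ± 2.41 CPM in controls and had no count in mutants, at least 643-fold lower (adjusted p = 2.17e-05).

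Lineage transcription factors and granule genes fell in the ileum too. Neurod1 had no count in the mutant libraries against 4.22 ± 1.03 CPM in controls, at least 345-fold lower (adjusted p = 2.57e-05), and Nkx2-2 and Rfx6 fell by 4.90 and 5.62 (adjusted p = 5.05e-05 and 6.09e-05). Of 12 transcription factor genes 11 fell, 12 when adjusted over the list alone (median log2 fold change -5.16, or -5.14 with 3 genes at their bound, camera adjusted p = 4.6e-11, but adjusted p = 0.14 with an estimated correlation). Of 21 genes of the secretory machinery 16 fell, 17 when adjusted over the list alone (median log2 fold change -0.94, camera adjusted p = 5.6e-07, but adjusted p = 0.46 with an estimated correlation), among them Chga, from 30.4 ± 6.71 to 1.04 ± 0.345 CPM (adjusted p = 9.28e-06), and Chgb, from 12.0 ± 2.83 to 0.164 ± 0.134 CPM (adjusted p = 6.74e-05). The receptor list was not called by camera (median log2 fold change -0.51, camera adjusted p = 0.28), with 4 of 12 lower and 3 higher, also when adjusted over the list alone. Ffar1 fell by 7.03 (SE 0.45, adjusted p = 1.41e-05) and the calcium-sensing receptor gene Casr by 3.82 (SE 0.56, adjusted p = 0.000594). The long-chain fatty acid receptor gene Ffar4 rose from 4.33 ± 0.617 to 7.55 ± 1.47 CPM (adjusted p = 0.00409) and Trpa1 from 2.07 ± 0.426 to 3.58 ± 0.909 CPM (adjusted p = 0.0194), although Trpa1 lost its call in 5 alternatives, among them the fits without control mice C134 and C154 and without mutant mice M167 and M177 (adjusted p of 0.00307 to 0.102 over all alternatives). Without control mouse C133 or C154, 2 receptor genes fell rather than 4.

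The ileum changed more widely than its hormone genes. Of 18310 genes tested, 3474 were higher and 2672 lower in mutants (8057 at an unadjusted p under 0.05), and 553 and 1150 of these differed at least 2-fold. In mutant ileum 20 of 20 proliferation genes and 19 of 25 cholesterol synthesis genes rose, while 15 of 15 T cell genes, 16 of 18 interferon response genes, 8 of 9 MHC class II genes and 11 of 17 peptide absorption genes fell. Without control mice C134 and C154 the counts over all genes were 2390 and 1677, and without mutant mice M167 and M177 they were 3512 and 2103. Tested against a fold change of 1.5 rather than against no change, 572 and 607 genes passed.

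The largest rises in mutant ileum again included Reg2, from 0.0826 ± 0.0952 to 27.9 ± 18.6 CPM (log2 fold change 8.36, SE 1.30, adjusted p = 0.00376), which moved with Ctrb1 there as well. Retnlb, an antibacterial product of goblet cells, rose from 0.314 ± 0.277 to 14.0 ± 11.6 CPM (adjusted p = 0.00623), and Akr1b8, an aldo-keto reductase gene, from 4.77 ± 0.894 to 47.8 ± 20.5 CPM (adjusted p = 0.000129). Il1rn, the antagonist of interleukin-1 receptors, rose from 5.35 ± 0.902 to 47.7 ± 23.7 CPM (adjusted p = 0.000289). Cwh43, Etv4 and Gml rose by 3.24, 3.47 and 3.09 on the log2 scale (adjusted p = 3.64e-05, 0.000472 and 0.00246), and Igfbp2 by 4.45 (adjusted p = 0.00497). Esr1 rose from 6.40 ± 0.511 to 31.6 ± 6.67 CPM (log2 fold change 2.33, SE 0.16, adjusted p = 1.89e-05). Reg2 and Igfbp2 lost their calls without control mice C134 and C154 and with limma-voom (adjusted p up to 0.171 and 0.0868 over all alternatives).

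Cell cycle genes rose throughout the list in mutant ileum. Rrm2, which makes deoxynucleotides for DNA synthesis, rose from 17.2 ± 1.27 to 54.6 ± 8.48 CPM (log2 fold change 1.70, SE 0.12, adjusted p = 2.17e-05). The replication helicase genes Mcm5 and Mcm3 rose from 34.9 ± 1.63 to 72.8 ± 2.74 CPM (adjusted p = 2.17e-05) and from 22.9 ± 0.839 to 47.2 ± 3.34 CPM (adjusted p = 3.61e-05), and Ccnb2, a mitotic cyclin gene, by 1.41. All 20 proliferation genes passed, also when adjusted over the list alone (median log2 fold change 0.99, camera adjusted p = 3.5e-14, but adjusted p = 0.14 with an estimated correlation), and 19 still rose without control mice C134 and C154 or without mutant mice M167 and M177. Genes of the serine and amino acid starvation response rose too, in 8 of 15 cases with none lower, also when adjusted over the list alone. Over these genes the median log2 fold change was 1.23 (camera adjusted p = 0.00048, but adjusted p = 0.51 with an estimated correlation). Psat1 and Phgdh of the serine pathway rose by 1.94 and 1.58 (adjusted p = 2.56e-05 and 5.21e-05), and Asns, asparagine synthetase, from 36.6 ± 1.62 to 99.9 ± 20.2 CPM (adjusted p = 4.29e-05). Chaperone genes of the endoplasmic reticulum rose in 8 of 14 cases with none lower, and 12 rose and 1 fell when adjusted over the list alone (median log2 fold change 0.48, camera adjusted p = 0.0048, but adjusted p = 0.64 with an estimated correlation), with Pdia6 up by 0.67 (adjusted p = 0.000305), and without mouse C134, C151, C154, M168 or M177 alone 5, 5, 4, 5 or 3 rose. Among genes of oxidative phosphorylation 9 of 20 rose and none fell, 10 when adjusted over the list alone (median log2 fold change 0.35, camera adjusted p = 0.016, but adjusted p = 0.70 with an estimated correlation), and this set was not called without mutant mouse M136 or M168 (adjusted p = 0.0552 and 0.0582). Without mouse C151, C154, M136, M167, M168 or M177, 3, 4, 4, 14, 4 or 4 of them rose. Agr2, a disulfide isomerase gene of goblet cells, rose from 203 ± 8.19 to 500 ± 88.1 CPM (adjusted p = 6.15e-05), while the goblet cell list split into 4 higher and 2 lower of 14, also when adjusted over the list alone, and was not called (camera adjusted p = 0.21).

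Sterol genes moved in opposite directions by function in mutant ileum. Of 25 genes of cholesterol synthesis 19 rose and none fell, 20 when adjusted over the list alone. The median log2 fold change of the list was 1.03 (camera adjusted p = 1.2e-08, but adjusted p = 0.46 with an estimated correlation). Lss rose from 28.4 ± 4.58 to 80.6 ± 14.6 CPM (adjusted p = 7.46e-05) and Mvd, mevalonate decarboxylase, by 1.52 (adjusted p = 9.24e-05). Of 10 sterol transport genes 6 fell and none rose, 7 when adjusted over the list alone. Their median log2 fold change was -0.68 (camera adjusted p = 0.0033, but adjusted p = 0.51 with an estimated correlation). The sterol exporter genes Abcg5 and Abcg1 fell from 130 ± 27.6 to 46.3 ± 15.3 CPM (adjusted p = 0.0027) and from 18.1 ± 1.61 to 7.82 ± 1.80 CPM (adjusted p = 0.000319). Fatty acid synthesis genes were not called as a set (7 of 15 higher and 1 lower, also when adjusted over the list alone, median log2 fold change 0.25, camera adjusted p = 0.24), with the elongase gene Elovl6 up by 0.74 (adjusted p = 0.000598) and Acly, which supplies acetyl-CoA, up by 0.58 (adjusted p = 0.00212). Without mouse C133 or M168, 4 of these genes rose.

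Digestive enzymes and transporters of the ileal brush border fell. Mep1a, a meprin metalloprotease gene, fell from 1348 ± 233 to 382 ± 66.5 CPM (log2 fold change -1.79, SE 0.17, adjusted p = 5.86e-05), and Anpep and Dpp4, which encode peptidases of the brush border, fell by 1.31 and 1.01 (adjusted p = 0.000199 and 0.000895). Of 17 genes of peptide and amino acid absorption 11 fell and none rose, 12 when adjusted over the list alone. The list had a median log2 fold change of -0.72 (camera adjusted p = 2.4e-05, but adjusted p = 0.51 with an estimated correlation). Lct, the lactase gene, fell by 2.23 (SE 0.32, adjusted p = 0.00119), and G6pc, glucose-6-phosphatase, by 1.77 (adjusted p = 0.00363, up to 0.0611 over all alternatives). The carbohydrate list had 4 of 13 genes lower and none higher, also when adjusted over the list alone. Across the list the median log2 fold change was -0.54 (camera adjusted p = 0.047, but adjusted p = 0.70 with an estimated correlation). Its call ended without control mouse C134 or mutant mouse M136, M167 or M177, with adjusted p of 0.00126 to 0.173 over the fits without 1 mouse and up to 0.533 over all alternatives. Without mutant mouse M168, 8 of these genes fell.

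Immune transcripts of the ileum fell across several cell types. The T cell genes Cd3e and Cd8a fell by 2.37 (SE 0.26, adjusted p = 0.000132) and 2.63 (SE 0.30, adjusted p = 0.000143). Itgae, an integrin gene of intraepithelial lymphocytes, fell from 16.5 ± 1.91 to 4.30 ± 1.03 CPM (adjusted p = 4.32e-05). All 15 T cell genes fell, also when adjusted over the list alone. Their median log2 fold change was -2.07 (camera adjusted p = 1.6e-09, but adjusted p = 0.46 with an estimated correlation). Cd74, the MHC class II invariant chain, fell from 1042 ± 399 to 163 ± 46.4 CPM (adjusted p = 0.000337) and Ciita, the transactivator of these genes, by 2.44 (adjusted p = 0.000129). Of 9 MHC class II genes 8 fell and none rose, also when adjusted over the list alone. Over these genes the median log2 fold change was -2.44 (camera adjusted p = 7.2e-06, but adjusted p = 0.51 with an estimated correlation). Of 18 interferon response genes 16 fell and none rose, 17 when adjusted over the list alone (median log2 fold change -1.57, camera adjusted p = 1.2e-08, but adjusted p = 0.46 with an estimated correlation), with Ddx60 down from 35.8 ± 12.2 to 6.71 ± 1.34 CPM (adjusted p = 0.000132). Without control mice C134 and C154 the medians of these 3 lists were -1.88, -2.42 and -1.74, and 14, 8 and 15 of their genes still fell.

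Plasma cell and macrophage genes were lower as well. Jchain and Igha, which encode the joining chain and the heavy chain of IgA, fell from 1003 ± 199 to 305 ± 160 CPM (adjusted p = 0.00586) and from 2768 ± 641 to 1096 ± 452 CPM (adjusted p = 0.00709). Pigr, the receptor that carries IgA across the epithelium, fell from 2025 ± 238 to 880 ± 68.2 CPM (adjusted p = 6.45e-05). Of 15 B and plasma cell genes 13 fell and none rose, and 14 fell and 1 rose when adjusted over the list alone. The median log2 fold change of the list was -1.69 (camera adjusted p = 0.00014, but adjusted p = 0.51 with an estimated correlation). The lymphoid follicle list, whose transcripts were high in control mice C134 and C154, had 5 of 10 genes lower and none higher, and 7 lower and 1 higher when adjusted over the list alone. Its median log2 fold change was -2.43 (camera adjusted p = 0.0498, but adjusted p = 0.64 with an estimated correlation). Without these 2 mice 4 B and plasma cell genes passed, with a median of -1.22, and without mouse C134, C154, M136, M167, M168 or M177 alone 8, 7, 7, 7, 8 or 6 did. Jchain did not pass without the 2 (adjusted p = 0.0618, 0.000124 to 0.0618 over all alternatives). Without mutant mice M167 and M177, 3 passed and Igha did not (adjusted p = 0.0623, 3.25e-06 to 0.0623). Csf1r, the growth factor receptor gene of macrophages, fell by 0.87 (adjusted p = 0.00132), and in its list 11 of 14 genes fell and 1 (Mrc1) rose, with 12 lower when adjusted over the list alone. The list had a median log2 fold change of -0.69 (camera adjusted p = 0.00054, but adjusted p = 0.51 with an estimated correlation). Other defence genes went both ways, 5 of 17 higher and 4 lower, or 5 and 5 when adjusted over the list alone. Across the list the median log2 fold change was 0.27 (camera adjusted p = 0.93). Lcn2, an iron-binding antibacterial protein gene, rose by 1.28 (adjusted p = 0.00292), while Ubd and Reg3a fell by 3.49 and 2.21 (adjusted p = 0.000748 and 0.00341). Of 16 clock genes 1 rose and 4 fell, also when adjusted over the list alone, with Nr1d1 down from 120 ± 14.2 to 42.8 ± 7.46 CPM (adjusted p = 6.02e-05), Bhlhe41 down by 1.80 (adjusted p = 0.000756) and Cry1 up by 0.70 (adjusted p = 0.00358). The clock list was not called (median log2 fold change -0.22, camera adjusted p = 0.16) but was without control mouse C154 (adjusted p = 0.0193, 0.0162 to 0.299 over all alternatives).

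**Figure D3:**
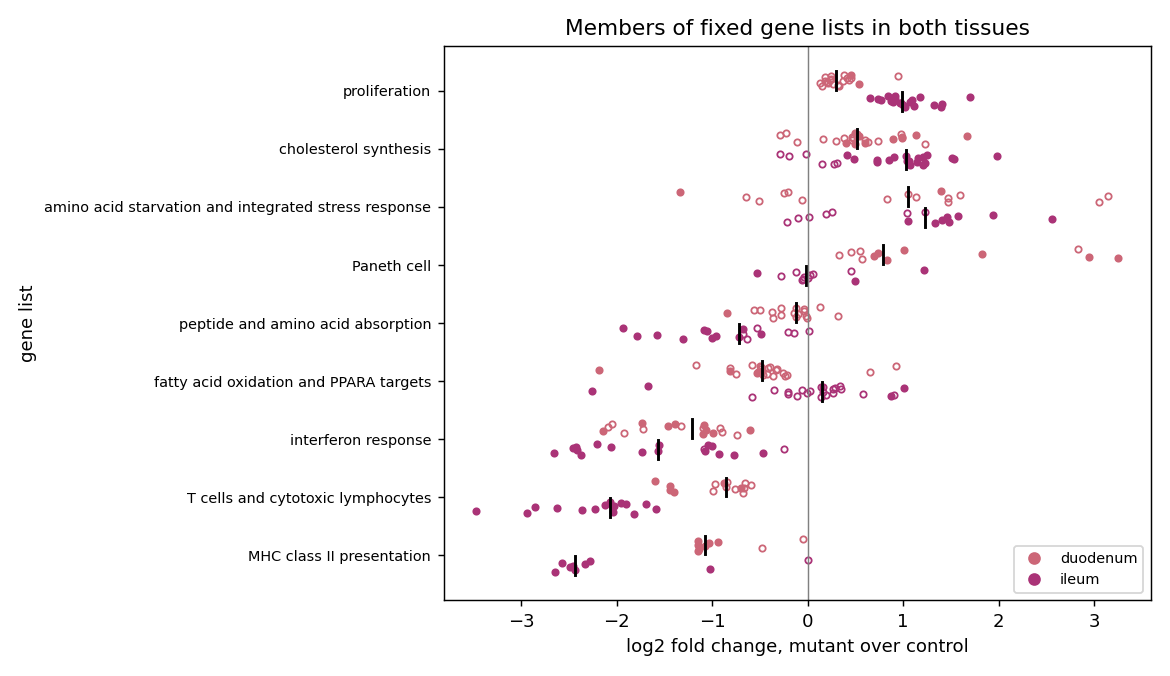
Log2 fold changes, mutant over control, of the members of 9 gene lists in duodenum and ileum; filled points passed an adjusted p of 0.05, open points did not, and black bars are medians. The medians of MHC class II, T cell and interferon response genes lie lowest in both tissues. They are -1.07, -0.86 and -1.21 in the duodenum and -2.44, -2.07 and -1.57 in the ileum.

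Both tissues shared part of the response. Among 17106 genes tested in both, 336 were higher in both tissues where 120 would be shared by independent lists of 598 and 3424 genes, and 517 were lower in both where 131 would be shared by lists of 868 and 2581. Of the genes called in duodenum 10 and 18 were called in the opposite direction in ileum, and 80.9 and 85.7% had the same sign there. Log2 fold changes of both tissues correlated across genes with a Pearson r of 0.52 (Spearman rho 0.29), or 0.46 without the enteroendocrine lists. Genes are not independent replicates, and the same mice gave both tissues. When the duodenum effect was taken from 2 control and 2 mutant mice and the ileum effect from the other 4 mice, the median r over 36 splits was 0.37 (0.16 to 0.57), against 0.50 with the same 4 mice in both tissues. The covariance was 0.206 with different mice and 0.258 with the same mice.

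The genotype effect itself differed between the tissues for 1734 of 19289 genes, 938 with a more positive and 796 with a more negative effect in the ileum. Among the contrasts with the smallest p-values were Trpa1, which fell in duodenum and rose in ileum (log2 fold changes -3.83 and 0.82, difference 4.63, SE 0.53, adjusted p = 0.000747), Cwh43 (-1.20 and 3.24, difference 4.43, SE 0.39, adjusted p = 4.02e-05) and Il1rn (-0.60 and 3.19, difference 3.77, SE 0.35, adjusted p = 8.72e-05). Col18a1, a basement membrane collagen gene, fell by 1.41 in duodenum with 0.22 in ileum (difference 1.61, SE 0.17, adjusted p = 0.000239). Tgfbi, a matrix protein gene induced by TGF-beta, had 0.06 in duodenum and fell by 1.70 in ileum (difference -1.78, SE 0.20, adjusted p = 0.000405), and Prlr, the prolactin receptor gene, had -0.27 and fell by 1.28 (difference -1.03, SE 0.13, adjusted p = 0.0013). Sae1, of the SUMO activating enzyme, and Abcb8, a mitochondrial transporter gene, differed by 1.30 and 0.96 (adjusted p = 0.000917 and 0.0013). With the mouse as a block 4027 genes differed, since each mouse gave both tissues. The fits that left out mice were run without the block. Without control mouse C133, C134, C151 or C154 the count was 333, 562, 184 or 577, without mutant mouse M136 or M177 it was 471 or 1060, and without control mice C134 and C154 together it was 22, among them Trpa1, Cwh43, Il1rn, Col18a1, Tgfbi and Sae1 but not Prlr and Abcb8 (adjusted p = 0.0676 for each, the highest over all alternatives).

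Proliferation genes rose more in the ileum than in the duodenum: for 14 of 20 the difference passed, 18 when adjusted over the list alone (median difference 0.69, camera adjusted p = 1e-09, but adjusted p = 0.93 with an estimated correlation). MHC class II and T cell genes had a more negative effect in the ileum for 7 of 9 and 6 of 15, or 8 and 10 when adjusted over the list alone (median differences -1.32 and -1.17, camera adjusted p = 0.00011 and 9.1e-05, but adjusted p = 0.93 for each with an estimated correlation). Cd74 differed by -1.51 (adjusted p = 0.0158) and Cd8a by -1.78 (adjusted p = 0.0213). The defensin gene Defa22 rose in the duodenum alone (log2 fold changes 2.95 and 0.00, difference -2.96, adjusted p = 0.00869), and 3 of 12 Paneth cell genes, 5 when adjusted over the list alone, had a more negative effect in the ileum (median difference -0.71, camera adjusted p = 7e-05, but adjusted p = 0.93 with an estimated correlation). Cpt2 (difference 0.96, adjusted p = 0.0154) and 4 more of 24 fatty acid oxidation genes had a more positive effect in the ileum, 11 when adjusted over the list alone (median difference 0.54, camera adjusted p = 0.00076, but adjusted p = 0.93 with an estimated correlation). The same held for 3 of 20 oxidative phosphorylation genes, 6 when adjusted over the list alone (median difference 0.38, camera adjusted p = 8.9e-05, but adjusted p = 0.93 with an estimated correlation). In this fit, which had no block for the mouse, no difference passed for the 18 interferon response genes, also over the list alone (median difference -0.23, camera adjusted p = 0.77). Without mouse C133, C134, C151, C154, M136 or M167 the difference passed for 2, 2, 1, 2, 1 or 9 proliferation genes, and without C133, C134, C154, M136, M167 or M177 for 0, 1, 3, 0, 3 or 2 MHC class II genes. For T cell genes it passed in 0, 0, 1, 1, 0, 3 or 3 cases without C133, C134, C151, C154, M136, M167 or M177, and for Paneth cell genes in 1 case without C151. For fatty acid oxidation genes it passed in 2, 3, 0, 2, 2, 8, 3 or 2 cases without C133, C134, C151, C154, M136, M167, M168 or M177. For oxidative phosphorylation genes it passed in 0 cases without C133, C134, C151, M136 or M177 and in 8 without M167. Some calls of single genes here ended when a mouse was left out. Cd74 lost its call without C133, C134 or M136 (adjusted p up to 0.0576, and up to 0.107 over all alternatives). Cd8a lost its call without C133, C134, C151 or M136 (up to 0.0747 and 0.133) and Cpt2 without C151 (0.0676, and up to 0.0975). Without control mice C134 and C154 no gene of the proliferation, MHC class II, T cell, fatty acid oxidation or oxidative phosphorylation lists passed, nor did Defa22 (adjusted p = 0.0838), although the camera calls for these lists held.

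The regional identity of the tissues was plain in the control mice. Fabp6, the ileal bile acid binding protein gene, stood at 1149 ± 463 CPM in ileum and 0.120 ± 0.0844 CPM in duodenum (log2 fold change, ileum over duodenum, 13.18, SE 0.66, adjusted p = 3.33e-06), and Slc10a2, the ileal bile acid transporter gene, at 521 ± 160 and 2.40 ± 0.398 CPM (adjusted p = 2.63e-07). Slc5a8, a transporter gene of short-chain fatty acids, was higher in ileum by 12.11 (SE 0.21, adjusted p = 1.74e-10). Hoxc8 had no count in duodenum and was at least 610-fold higher in ileum (adjusted p = 2.27e-07), and Hoxb9 stood at 13.2 ± 8.03 CPM in ileum against 1 count in duodenum, a ratio of 2859 with an interval of 513 to 112961 (adjusted p = 0.000565). All 11 distal position genes were higher in ileum, also when adjusted over the list alone. Their median log2 fold change was 5.93 (camera adjusted p = 4.5e-07, and adjusted p = 0.046 with an estimated correlation). In the other direction, Gata4, a transcription factor gene of the proximal gut, stood at 24.7 ± 10.6 CPM in ileum and 215 ± 9.78 CPM in duodenum (adjusted p = 3.66e-05), and Reg1 at 37.7 ± 23.5 and 2249 ± 1088 CPM (adjusted p = 0.000488). Aqp8, Otop3 and the predicted gene AC102159.1 were lower in ileum, with log2 fold changes of -6.34, -5.24 and -5.65 (adjusted p = 6.06e-06, 0.00195 and 0.000735). Of 9 proximal position genes 8 were lower, also when adjusted over the list alone. Over these genes the median log2 fold change was -3.11 (camera adjusted p = 0.00091, but adjusted p = 0.26 with an estimated correlation). Fgf15 and Abca12 had no count in duodenum and were at least 1771-fold and 2134-fold higher in ileum (adjusted p = 0.018 and 0.0441), calls that Fgf15 lost without control mouse C134 or C154 (up to 0.0757) and Abca12 without C133, C151 or C154 (up to 0.147, and up to 0.153 over all alternatives). The calcium binding gene S100g (log2 fold change -6.22, adjusted p = 0.0109) lost its call without C133 or C151 (up to 0.0593) and the alkaline phosphatase gene Akp3 (log2 fold change -5.23, adjusted p = 0.0136) without C133, C151 or C154 (up to 0.0732). Levels of some of these genes also differed between control mice. In the duodenum of C133, C134, C151 and C154, S100g stood at 258, 14.3, 446 and 55.1 CPM and Akp3 at 7355, 545, 6836 and 4147 CPM. Hoxb9 stood at 18.0, 1.54, 19.0 and 14.3 CPM in their ileum. Gata4 varied less in their duodenum, at 227, 204, 219 and 211 CPM. Whether the sampled position differed between mice was not tested.

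Nutrient handling followed the same axis in controls, with 5109 genes higher and 5511 lower in ileum among 18217 tested. Of 24 lipid uptake genes 20 were lower in ileum and 1 higher, also when adjusted over the list alone. The median log2 fold change of the list was -1.18 (camera adjusted p = 5.8e-06, but adjusted p = 0.53 with an estimated correlation). Fabp1, a fatty acid binding protein gene, stood at 194 ± 36.6 CPM in ileum and 2790 ± 584 CPM in duodenum (adjusted p = 2.39e-07). The 13 carbohydrate and 20 oxidative phosphorylation genes were all lower, also when adjusted over the list alone (median log2 fold changes -2.31 and -1.25, camera adjusted p = 7.8e-07 and 4.2e-10, but adjusted p = 0.53 for each with an estimated correlation). All 12 Paneth cell genes were higher in ileum, also when adjusted over the list alone (median log2 fold change 1.69, camera adjusted p = 1.6e-06, but adjusted p = 0.53 with an estimated correlation), with Itln1, an intelectin gene, at 3107 ± 445 against 1029 ± 112 CPM. In mutant mice 2301 genes were higher and 3246 lower in ileum among 17852 tested, and the difference between mutants and controls in this contrast is the genotype by tissue comparison above. Without control mice C134 and C154 the control counts were 5081 and 5110, and without mutant mice M167 and M177 the mutant counts were 1709 and 2569.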

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

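The tests of explanations and the splits of the mice in this part were chosen after the results were seen.

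Dixon's Q picks out about 1 in 20 groups by chance where values are normally distributed, which need not hold for CPM. A single library lay far from the other 3 of its group for 13 of 163 groups tested with it. These were Neurog3 in the ileum of control mouse C154 (0.560 CPM), Gcg in the duodenum of mutant mouse M177 (3.68), Cck in the ileum of mutant mouse M168 (0.0697), Chga in the duodenum of control mouse C133 (82.0) and Reg2 in the duodenum of control mouse C151 (4.17). Further cases were Nts in the ileum of control mouse C134 (80.6), Il1rn in the ileum of mutant mouse M167 (83.1), Neurod1 in the duodenum of mutant mouse M168 (0.104), Tgfbi in the ileum of mutant mouse M168 (152) and Sae1 in the duodenum of mutant mouse M167 (30.4). The last were Prlr in the ileum of mutant mouse M136 (148), Abcb8 in the ileum of mutant mouse M167 (35.4) and Hoxb9 in the duodenum of mutant mouse M167 (0.0708). The values of Cck, Neurod1 and Hoxb9 rested on 4, 5 and 3 counts, against 0, 0 and 1 in each other library of the group.

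For 50 named genes the genotype effect differed between the tissues. Among those followed through the 8 fits without 1 mouse, Ccna2, Ndufs1 and Uqcrfs1 lost their calls in 5 and Cd3e and Cd8a in 4. Cd74 lost its call in 3, Birc5 and Ciita in 2, and Acadl, Cpt2, Defa21 and Ffar4 in 1. In log2 units, ileum effect minus duodenum effect, enteroendocrine and sensing genes gave Pyy -8.38, Nkx2-2 -2.71, Ffar1 -2.77, Ffar2 0.95, Ffar4 1.41, Sst 1.21 and Trpa1 4.63. In the duodenum of mutant mice M136, M167, M168 and M177, Pyy stood at 0, 0.472, 0.543 and 0.969 CPM and Nkx2-2 at 0.139, 0.661, 0.292 and 0.443 CPM, beside a mean of the pancreatic islet genes of -0.47, 1.99, 2.25 and 2.87 (log2 CPM). Genes among the largest rises gave Reg3b -4.41, Cfap61 -3.09, Esr1 -1.34, Igfbp2 4.01, Akr1b8 3.01, Cwh43 4.43 and Il1rn 3.77. Immune genes gave H2-Eb1 -1.15, H2-Ab1 -1.33, H2-Aa -1.44, Ciita -1.31, Cd74 -1.51, Cd4 -0.91, Itgae -1.05, Cd3e -1.62, Cd8a -1.78 and Jchain -1.29. Paneth, goblet and absorption genes gave Defa22 -2.96, Defa21 -3.31, Agr2 0.97, Mep1a -1.78 and G6pc -3.01. Metabolic genes gave Cpt2 0.96, Cpt1a 0.77, Acadl 1.33, Ndufs1 0.55, Uqcrfs1 0.74, Mvd 1.03, Acat2 0.56, Abcg1 -1.74 and Mylip -1.60. Cell cycle and clock genes gave Mcm5 0.64, Mcm3 0.68, Ccna2 0.76, Ccnb2 1.17, Birc5 1.23, Nfil3 -1.63 and Cry2 -0.73. The remaining ones were Col18a1 1.61, Tgfbi -1.78, Sae1 1.30, Prlr -1.03 and Abcb8 0.96.

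For the genotype comparisons, only 1 of the 35 splits of the 8 mice into 4 and 4, the real one, gave as many genes. The real split gave 1506 in duodenum against at most 2, 6146 in ileum against at most 0, and 1734 in the genotype by tissue comparison against at most 0 in edgeR. A share of 1 in 35 is the smallest these splits can give, so they argue against chance no further than that. All other splits mix control and mutant mice, so a real difference between the genotypes would itself keep their counts low. Nor can the splits tell genotype from another factor that parted the same mice. For the tissue contrasts the 8 splits that part all 4 pairs of libraries from the same mouse are too few for a share under 0.05, with 10620 genes in controls and 5547 in mutants for the real split against at most 0 for any other of these in edgeR. Among splits that part fewer pairs, that of control mice C133 and C151 against C134 and C154 gave 3 genes and the others, in controls and mutants, gave 0.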

How the results depend on the processing

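The fits without control mice C134 and C154 or mutant mice M167 and M177, and those with the exocrine pancreas or lymphoid follicle genes as a covariate, were chosen after the results were seen. In duodenum, against 606 higher genes, DESeq2 gave 1387, all 16 libraries in 1 fit 1202, the smooth muscle covariate 355, the pancreas covariate 47, the follicle covariate 223 and the test against a fold of 1.5 gave 21. Without mutant mice M167 and M177 there were 140, and without control mice C134 and C154 there were 37. Against 900 lower genes, the same alternatives gave 1585 (DESeq2), 449 (muscle), 193 (pancreas), 541 (follicle), 101 (fold of 1.5), 305 and 163. Without mouse C133, C134, C151, C154, M136, M167, M168 or M177 the higher genes were 131, 129, 124, 216, 1025, 314, 916 or 216 and the lower ones 410, 413, 352, 476, 1114, 547, 1077 or 442. Of the 1506 calls 184 were kept without control mice C134 and C154. In ileum, 3474 higher genes became 572 against a fold of 1.5, and 2672 lower genes became 607, 1676 with the follicle covariate and 1677 without control mice C134 and C154, with 3748 of the 6146 calls kept. The 1734 genes of the genotype by tissue comparison became 3199 with DESeq2 and 4027 with the mouse as a block. In the fits that left out mice, which had no block, they were 22 without control mice C134 and C154. Without mouse C133, C134, C151, C154, M136 or M177 they were 333, 562, 184, 577, 471 or 1060, and without M168 they were 2009. With the block, 5423 genes were higher and 5832 lower in ileum of control mice (5109 and 5511 without it) and 3058 and 3893 in mutant mice (2301 and 3246), and 15 rather than 11 lists were called in the genotype by tissue comparison and 16 rather than 14 between tissues of control mice. Of the genes and lists followed singly under the block, it changed no other call.

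With an estimated correlation 2 of 17 lists were called in duodenum, 1 of 21 in ileum, 0 of 11 in the genotype by tissue comparison and 1 of 14 between tissues of control mice, and fry called 11, 19, 4 and 30. Without a low count filter 24 lists rather than 14 were called between tissues. The correlation of both tissues, 0.519, was 0.365 with different mice. Among uncalled lists, the duodenal antimicrobial median of 0.31 was 0.567 without mutant mouse M136, and the duodenal clock median of -0.06 was -0.257 without control mouse C154. Medians changed sign for lists that were not called either way: duodenal antimicrobial genes without mutant mouse M168 (-0.152), duodenal clock genes without mutant mouse M177 (0.00875) and without M167 and M177 (0.0955), ileal receptors at 1 CPM (0.229) and ileal antimicrobial genes without M167 and M177 (-0.0696).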

Other observations

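The gene lists in this part were set before the data were examined, but which of them to describe, the genes named here and the tests of the 3 explanations were chosen after the results were seen.

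In mutant ileum, tuft cell genes fell in 3 of 13 cases and none rose, also when adjusted over the list alone (median log2 fold change -0.55, camera adjusted p = 0.024, but adjusted p = 0.64 with an estimated correlation), with the marker gene Dclk1 at -0.64 (adjusted p = 0.027). Enteric neuron genes fell in 4 of 13 cases and none rose, 3 when adjusted over the list alone (median log2 fold change -0.50, camera adjusted p = 0.029, but adjusted p = 0.64 with an estimated correlation), among them the neuropeptide gene Vip at -1.25 (adjusted p = 0.00016). In mutant duodenum the median of this list was 0.15, although its lowest member stood at -4.53. Which cells the ileal falls came from was not tested. Of 16 mineral and vitamin absorption genes in mutant ileum 8 fell and 1 rose, also when adjusted over the list alone (median log2 fold change -0.44, camera adjusted p = 0.045, but adjusted p = 0.51 with an estimated correlation), including Cubn, the cobalamin receptor gene, at -1.72 (adjusted p = 0.00012). The stem cell list was not called (2 of 11 lower, also when adjusted over the list alone, camera adjusted p = 0.14), although Olfm4 fell by 1.28 (adjusted p = 0.0013). In the duodenum, 3 of 11 fibroblast genes fell, 5 when adjusted over the list alone (median log2 fold change -0.37, camera adjusted p = 0.0039, but adjusted p = 0.44 with an estimated correlation), with the collagen gene Col3a1 at -1.24 (adjusted p = 0.0018). The near-identical mast cell protease genes Mcpt1 and Mcpt2 fell there by 1.98 and 2.01 (adjusted p = 0.0088 and 0.0064). For the lists of this paragraph the alternatives are tabulated only within the number of all lists called, not list by list.

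Reg2 rose in both tissues in step with Ctrb1, at 7.82 to 12.3% of it in the 8 mutant libraries and 0.0170 to 0.186% in control mice C133 and C151. A source of Reg2 in the intestinal wall alone is argued against, because the ratio spread 1.57-fold over the mutant libraries while Ctrb1 spread 1820-fold and Reg2 1431-fold. Pancreatic RNA with the Reg2 content of the controls is argued against as well, since the lowest mutant ratio was 42.0 times the highest control ratio. Pancreatic RNA that is richer in Reg2 in mutant mice may explain the pattern, and the ratio spread of 1.57 is what it needs. Why such RNA reached these libraries, with Ctrb1 at 35170 and 35135 CPM in the duodenum of mutant mice M167 and M177, stays open.

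Esr1 rose in both tissues, and the CreERT2 transgene holds a ligand-binding domain of the oestrogen receptor under the Villin promoter. Transcripts of the transgene may have been counted as Esr1. In mutants the ratio of Esr1 to Vil1, the Villin gene, was 1.33 to 1.75% and varied less (log2 SD 0.148, median of other genes 0.434) than for all but 0.353% of 1984 genes with at least 100 CPM, as that explanation needs. Of 4 tests of Greb1 and Pgr, targets of the receptor, 0 passed upward and Pgr fell in ileum by 1.91 on the log2 scale (adjusted p = 0.00296). A receptor without ligand need not raise its targets, so these tests cannot decide whether the mouse gene was transcribed more. Gene counts do not place reads within Esr1, so its source stays open.

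The fall of T cell, MHC class II and interferon transcripts in mutant ileum might have come from the follicle transcripts of control mice C134 and C154. Without these mice the medians of the 3 lists were -1.88, -2.42 and -1.74, which argues against that for them. Of the B and plasma cell genes 13 fell with these mice and 4 without them, with a median that stayed negative. As few passed without mutant mice M167 and M177, so these counts cannot decide the question for B and plasma cell genes. An equal loss of all leukocytes is argued against by the T cell median lying -1.38 from the macrophage median (permutation p = 5e-05, two-sided, 15 and 14 genes). Genes of a list are not independent, so this p-value is likely too small. Whether housing or collection day differed between the genotypes is not given in the sources used here, and a role of either stays open.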
